A study of Homo sapiens with 9 samples.

How the data were processed

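RNA sequencing measured gene expression in 9 samples of human neural progenitor cells, 3 labelled wild type and described as siRNA samples marked NC (called control here) and 3 for each of 2 siRNAs against GNL3. Groups and replicate numbers were taken from the sample labels. The deposited table gives, for each library, expected counts per gene, which are estimates that need not be whole, and TPM, a transcript abundance in which the authors scaled length-corrected abundances to the same total in each library. Per the submitters' processing notes, the tools were STAR 2.4.2a, an aligner, RSEM 1.3.0, an estimator of transcript abundance, and DESeq2 1.14.1, on the human genome build hg19. The parameters, the annotation and whether counting used the strand of the reads are not given in the sources used here. Values of overlapping, antisense or near-identical genes are therefore uncertain.

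Expected counts as deposited were rounded to whole numbers. Between 9.46% and 12.0% of values per library were fractional. The table holds 57820 Ensembl gene IDs, of which 39538 were named from a current table of gene names, 12800 only from GENCODE 29, and 5482 have no name here. A further 47 IDs, which mark second copies of genes shared by the sex chromosomes, were included in that number and hold 76385 reads over all libraries. No coordinates are given, because the reference used here is of another genome build than the deposited values. Library totals were 32020908 to 36271690 counts, and fold change intervals are at 95% by a normal approximation from the SE. With 3 libraries per group such intervals are somewhat too narrow. Counts of 0 were treated with a floor of 3 reads over the group, which like the intervals of counts covers counting error only. Of all counts, 6 abundant noncoding RNAs (7SK, RMRP, SNORD3A, AL355075.4 and 2 IDs without a name) took 6.36% to 15.3%, and of TPM 45.2% to 66.1%, the most in siRNA 1 replicate 1, so TPM of other genes depend on them. Replicates differed beyond sampling noise in every pair, so each library counted as 1 replicate.

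Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The test was edgeR's robust quasi-likelihood test with TMM factors and the filterByExpr filter, in 1 fit over the 3 groups with 6 residual degrees of freedom, which tested 20214 genes at a common biological coefficient of variation of 0.191. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were siRNA 1 against control, siRNA 2 against control, genes called in the same direction with both, and siRNA 1 against siRNA 2. Log2 fold changes are those of the edgeR fit and CPM use TMM-scaled library sizes.

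The 29 gene lists were tested with limma's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists within a comparison. They are G1/S phase genes, G2/M phase genes, p53 target genes, ribosome biogenesis factors, cytosolic ribosomal proteins, neural progenitor and radial glia markers, neuronal differentiation markers, synapse genes, glial markers, pluripotency markers, mesenchymal and neural crest markers, endothelial and blood cell markers, interferon response genes, cholesterol synthesis genes, unfolded protein and integrated stress response genes, heat shock genes, immediate early genes, DNA repair and replication stress genes, shelterin and telomerase genes, extracellular matrix genes, axon guidance genes, Notch pathway genes, Wnt pathway genes, glycolysis and hypoxia genes, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, replication-dependent histone genes, neighbours of GNL3 on chromosome 3, and GNL3-related GTPases. Of their genes, 49 matched no ID, among them part of the histone and oxidative phosphorylation lists. Some genes stand in more than 1 list.

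Genes were named by a rule. For each comparison with control it took the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean of at least 5 CPM in a compared group and no overlap between replicates of the groups. For both siRNAs it took up to 12 genes in each direction, ranked by the smaller change, and between the siRNAs 5 in each direction. It also took up to 4 called members of each list, those with the smallest p, and GNL1, GNL2, GNL3L and the neighbours of GNL3. Genes named as small nucleolar RNAs, microRNAs, pseudogenes or clones were passed over, and genes whose level tells sex were never named. MSMO1, SC5D, SEMA3D, SEMA6D, ENO2, L1TD1, the list members given for the comparison between siRNAs, LEFTY1 in both of its comparisons, and the genes that open the last part of the closing section were chosen after their values were seen. Results of some single genes are not reported here.

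The grouping, tests, lists, naming rule and the alternatives listed next were chosen before the data were examined. These were DESeq2, RLE and upper-quartile factors, no filter on low counts, at least 1 CPM in 3 libraries, only the groups compared, the replicate number as a block, limma-voom, limma-trend on log2(TPM + 1) for genes with a TPM of at least 1, an absolute log2 fold change of at least 1, leaving out each library in turn, and for lists an estimated correlation and fry. Restricting to protein-coding genes and removing a smooth trend on GC content and transcript length were added after seeing the data.

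The procedures were tested on simulated counts with 200 changed genes. These were drawn from genes with a mean of at least 5 CPM, so recovery of less abundant genes was not tried. In data simulated for siRNA 1 against control over 19670 genes, 29 of 67 genes changed 1.5-fold were called, 61 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 7 unchanged genes called. For siRNA 2 against control the numbers were 32 of 66, 57 of 67 and 66 of 67, with 12 unchanged genes called. Of 100 genes changed in both, 70 were called in both, and no other gene was. A list shifted by −0.25 had a camera adjusted p of 2.12e-14, and 0 other lists were called. The simulated genes varied independently, so this does not test camera on lists whose genes vary together. The search for sequence words covered 15902 words of 7 bases found in at least 100 of 14016 genes with a 3′ untranslated region of at least 100 bases, against 100 permutations. Of 50 words of intermediate frequency, given a fall of 0.1 in every gene that holds them, it found 98% with siRNA 1, 100% with siRNA 2 and 100% between the siRNAs. The rarest and the most common words, and falls in only some of the genes, were not tried.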

Results

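RNA sequencing was performed on 9 samples of human neural progenitor cells, the dividing precursors of neurons and glia. GNL3, the gene of the nucleolar GTP-binding protein nucleostemin, had been knocked down in 6 of them by RNA interference, with 3 samples for each of 2 small interfering RNAs, called siRNA 1 and siRNA 2 here. The other 3 samples served as controls; they are labelled wild type and, in their descriptions, as siRNA samples marked NC, an abbreviation the labels do not spell out. The siRNA was given at 20 nM with a lipid transfection reagent, and RNA was extracted 48 h later. The question the design addresses is which genes respond to the loss of GNL3. Total counts were 34100944, 36271690 and 35512133 in control replicates 1 to 3, 35753125, 34927430 and 34738554 with siRNA 1, and 32485475, 35112161 and 32020908 with siRNA 2. Genes with a count above 0 numbered 24223 in siRNA 1 replicate 2, 25752 in siRNA 1 replicate 3 and 26919 to 28451 in the other 7 libraries. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

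Genes of the pluripotent state were abundant in all 9 libraries. LIN28A, an RNA-binding protein of stem cells, averaged 2300 ± 361 CPM (counts scaled to the library total; SD, n = 9). POU5F1, a core pluripotency transcription factor, averaged 1159 ± 205 CPM, the DNA methyltransferase gene DNMT3B 1137 ± 175 CPM and DPPA4 760 ± 110 CPM. Of the 18 pluripotency markers fixed in advance, 12 exceeded 10 CPM in every library. Of the transcription factor genes on the list of neural progenitor markers, PAX6, SOX1 and HES5 were scarce, with 2.23 ± 0.368, 4.27 ± 1.08 and 1.48 ± 0.623 CPM, while OTX2 and SOX11 averaged 104 ± 13.5 and 184 ± 20.2 CPM. NES and SOX2, which neural progenitors and pluripotent cells both express, averaged 406 ± 54.9 and 127 ± 16.9 CPM. POU5F1 has processed copies elsewhere in the genome that can share its reads, so its own level is uncertain.

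**Figure D1:**
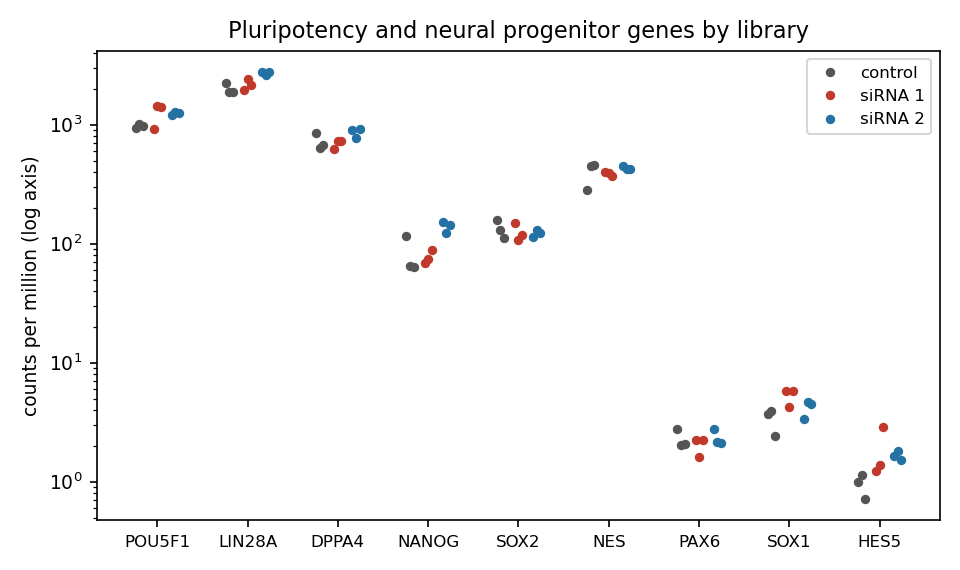
CPM on a log axis for pluripotency and neural progenitor genes, with 1 point per library coloured by group. POU5F1 and LIN28A lie near or above 1000 CPM in all 9 libraries, while PAX6, SOX1 and HES5 lie below 10 CPM.

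GNL3 (ENSG00000163938.12) was lower in all 6 knockdown libraries than in any control library. Control libraries held 280, 283 and 316 CPM, siRNA 1 libraries 109, 121 and 110 CPM, and siRNA 2 libraries 126, 109 and 133 CPM. The means were 293 ± 20.0 CPM in controls, 114 ± 6.68 CPM with siRNA 1 and 123 ± 12.2 CPM with siRNA 2 (SD, n = 3 each). With siRNA 1, GNL3 fell to 38.8% of control (95% interval 33.2% to 45.4%), a log2 fold change of −1.37 (SE 0.12, adjusted p = 2.80e-07 by edgeR's quasi-likelihood test). With siRNA 2 it fell to 42.0% of control (35.9% to 49.1%), a log2 fold change of −1.25 (SE 0.12, edgeR adjusted p = 1.83e-05). The siRNAs differed in GNL3 by −0.11 (SE 0.11; interval −0.34 to 0.11), which did not pass the edgeR test (adjusted p = 0.652). With limma on log2(TPM + 1) the siRNA 2 fold change was −0.83 and its call was lost (adjusted p = 1.00; range over its alternatives 2.06e-23 to 1.00).

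**Figure D2:**
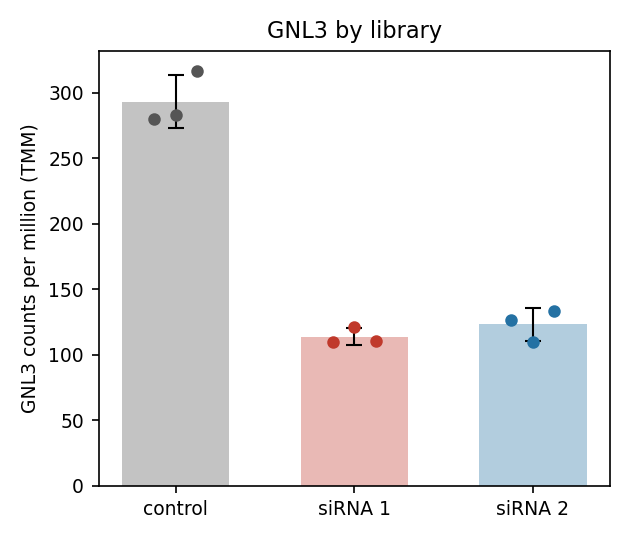
GNL3 in CPM by group. Bars are means of 3 libraries, error bars are SD and points are libraries; the 6 knockdown libraries lie between 109 and 133 CPM and the controls between 280 and 316 CPM.

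Of the genes related to GNL3, GNL3L, its nearest paralog, had log2 fold changes of 0.04 with siRNA 1 and 0.19 with siRNA 2, and GNL1 0.09 and 0.17, none past the edgeR test (adjusted p from 0.721 to 0.919). GNL2, a GTPase of ribosome assembly, fell by 0.43 with siRNA 1 (SE 0.12, edgeR adjusted p = 0.0409) and stood at −0.36 with siRNA 2 (adjusted p = 0.361). Its call was lost in each fit that left out 1 library except those without control replicate 1 and siRNA 1 replicate 1. Of 15 measured neighbours of GNL3 on chromosome 3, 1 fell with siRNA 1: TNNC1, the gene of a muscle troponin, at −1.08 (SE 0.30, adjusted p = 0.0377), a call lost in 6 of the 9 fits without 1 library (control replicates 2 and 3, siRNA 1 replicates 1 and 2, siRNA 2 replicates 1 and 3).

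With siRNA 1, antiviral genes that cells switch on after interferon led the rises among called genes that met the naming rule. RSAD2, which codes for the antiviral protein viperin, rose from 0.381 ± 0.0590 to 158 ± 13.3 CPM (log2 fold change 8.68, SE 0.18, edgeR adjusted p = 4.74e-15). The sensors of double-stranded RNA OAS2 and OASL rose by 7.35 and 7.23, and the chemokine gene CXCL10 by 7.08. IFI27 rose by 6.95, APOL1 by 6.04, TNFSF10, the gene of the death ligand TRAIL, by 5.96, and RTP4 by 7.97, the last from 5 control reads in total. Among called genes of at least 5 CPM in a compared group, the falls were smaller than these rises. MMRN1, which codes for a large secreted glycoprotein, fell by 2.10, the cytokine gene IL33 by 1.86, the transcriptional cofactor gene ANKRD1 by 1.86, PAMR1 by 1.49 and the thiamine transporter gene SLC19A3 by 1.35. STON1, an endocytic adaptor gene, fell too (adjusted p = 8.23e-06 by edgeR). CLEC18A stood at −1.55, but its reads can be shared with near-identical family members and its own change is uncertain.

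All 46 measured interferon response genes rose with siRNA 1, with a median log2 fold change of 3.85, and all 46 passed when adjusted over the list alone (camera adjusted p = 5.72e-85; adjusted p = 0.00923 with an estimated correlation). The list median lay above that of every control in 3 of 3 libraries, and examples are IFIT2 at 5.88 and CMPK2 at 5.70. IFNB1, interferon beta itself, had 44, 61 and 62 reads in the siRNA 1 libraries and 0 in the controls, at least 55.9-fold higher at a floor of 3 reads over the control group. Of 36 p53 target genes, 23 rose and 1 fell, with a median of 0.64, and 24 rose and 3 fell when adjusted over the list alone (camera adjusted p = 8.99e-14; adjusted p = 0.0250 with an estimated correlation). BTG2, an antiproliferative gene, rose by 1.47, CDKN1A, the inhibitor of cyclin-dependent kinases, by 1.24, the DNA damage-binding gene DDB2 by 1.19 and the death receptor gene TNFRSF10B by 1.13.

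Of 29 immediate early genes, 7 rose with siRNA 1, and 9 rose and 2 fell when adjusted over the list alone. KLF4 rose by 1.86, EGR1 by 1.81 and IER2 by 0.82, all transcription regulators induced within minutes of a stimulus (camera adjusted p = 0.00241; adjusted p = 0.338 with an estimated correlation). Of 43 G1/S genes, which serve DNA replication, 6 fell, with a median of −0.24, and 1 rose and 17 fell when adjusted over the list alone. The helicase subunit gene MCM6 fell by 0.73 and the histone mRNA-binding gene SLBP by 0.53 (list camera adjusted p = 4.03e-06; adjusted p = 0.192 with an estimated correlation). Of 54 G2/M genes, CKS2 and TTK fell, by 0.60 and 0.61, and the mitotic kinase gene PLK1 rose by 0.47, the same counts as adjusted over the list alone. The list was lower (camera adjusted p = 0.0461; adjusted p = 0.338 with an estimated correlation), but not without control replicate 3, siRNA 1 replicate 2, siRNA 1 replicate 3 or siRNA 2 replicate 1, where its adjusted p reached 0.105. Of 19 glial markers, 3 fell, among them S100B by 1.07 and CD44 by 0.79, and the myelin enzyme gene CNP rose by 1.19, with 1 higher and 6 lower when adjusted over the list alone. The glial list was lower (camera adjusted p = 0.0177; adjusted p = 0.176 with an estimated correlation), but not without siRNA 1 replicate 1 (adjusted p = 0.0801). The calls of TTK and PLK1 were lost without control replicate 3 or siRNA 1 replicate 2, and that of CD44 without control replicates 1, 2 or 3, siRNA 1 replicate 3 or siRNA 2 replicate 3.

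In all, 1373 of 20214 genes passed the edgeR test with siRNA 1 (Benjamini-Hochberg), 762 higher and 611 lower. With upper-quartile scaling the balance turned, with 677 higher and 847 lower. The count was 590 without control replicate 3, 709 without siRNA 1 replicate 2, 873 without siRNA 1 replicate 3, 2065 with DESeq2 and 196 with limma on log2(TPM + 1). The 6 lists called became 13 without control replicate 1.

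siRNA 2 raised members of the same antiviral families by less. OAS2 rose by 2.75 (SE 0.21, edgeR adjusted p = 6.53e-06), from 1.24 ± 0.434 to 8.34 ± 1.59 CPM. OAS1, MX1 and OAS3 rose by 2.07, 2.04 and 1.63, and SAMD9 and IFIT1 by 1.61 and 1.55. CDKN1A rose by 1.53, from 30.1 ± 5.77 to 87.2 ± 15.1 CPM. MIR205HG, the host transcript of a microRNA, rose by 1.78. Besides GNL3, the genes with the largest falls among called genes of at least 5 CPM in a compared group and no overlap of replicates were F13A1, the gene of a blood coagulation factor subunit, at −1.56, LRRC17 at −0.85, the kinase gene ALPK2 at −0.76, the glycosyltransferase gene GCNT4 at −0.74, the guidance cue gene SEMA3C at −0.70, DOCK9 at −0.69 and the glycolytic regulator gene PFKFB4 at −0.69. Each of these 7 lost its call without control replicate 3, siRNA 2 replicate 1 or siRNA 2 replicate 3, with adjusted p of up to 0.339. Without siRNA 2 replicate 2, 6 of the 7 lost it, without control replicate 1 or siRNA 1 replicate 3 4 did, without control replicate 2 2 did, and without siRNA 1 replicate 1 1 did. IFIT1 lost its call without control replicate 3 (adjusted p = 0.0507).

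Of the 46 interferon response genes, 20 rose with siRNA 2, and 36 when adjusted over the list alone (camera adjusted p = 9.22e-40; adjusted p = 0.0348 with an estimated correlation). Their median log2 fold change was 0.76, or 0.74 with IFNB1 at its bound, above all controls in 3 of 3 libraries. Of the 36 p53 targets, 16 rose, with a median of 0.59 in 3 of 3 libraries above all controls, and 28 when adjusted over the list alone (camera adjusted p = 5.67e-33; adjusted p = 0.00455 with an estimated correlation). BTG2 and DDB2 rose by 1.26 and 1.24, and TNFRSF10B by 0.59, a call lost without control replicates 2 or 3 or any 1 siRNA 2 library. Of 18 pluripotency markers, the signalling gene NODAL and the noncoding ESRG rose, by 1.08 and 0.75, and 6 when adjusted over the list alone. The list median was 0.34 (camera adjusted p = 1.83e-06; adjusted p = 0.0519 with an estimated correlation). ESRG lost its call without control replicate 3, siRNA 2 replicate 1 or siRNA 2 replicate 3.

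Among 10 further lists called with siRNA 2, no more than 1 member passed over all genes, and each lost its call with an estimated correlation. Higher as lists were the immediate early genes (DUSP5 rose by 0.71; camera adjusted p = 0.00103; adjusted p = 0.273 with an estimated correlation), the synapse genes (camera adjusted p = 0.0189; adjusted p = 0.394 with an estimated correlation), the Notch pathway genes (camera adjusted p = 0.0189; adjusted p = 0.623 with an estimated correlation) and the neuronal differentiation markers (NHLH2 rose by 1.33; camera adjusted p = 0.0448; adjusted p = 0.394 with an estimated correlation). Their medians were 0.12, 0.10, 0.11 and 0.10, and 6, 0, 1 and 1 members rose when adjusted over the list alone. Lower as lists were the cholesterol synthesis genes (median −0.20; camera adjusted p = 8.28e-05; adjusted p = 0.132 with an estimated correlation) and the cytosolic ribosomal proteins (median −0.15; camera adjusted p = 8.28e-05; adjusted p = 0.735 with an estimated correlation). So were the unfolded protein and integrated stress response genes, in which ASNS, asparagine synthetase, fell by 0.68 (median −0.13; camera adjusted p = 1.11e-04; adjusted p = 0.132 with an estimated correlation). The glycolysis and hypoxia genes had a median of −0.14 (camera adjusted p = 0.00319; adjusted p = 0.273 with an estimated correlation), the G1/S genes −0.07 (camera adjusted p = 0.00443; adjusted p = 0.394 with an estimated correlation) and the extracellular matrix genes −0.11 (camera adjusted p = 0.0249; adjusted p = 0.735 with an estimated correlation). Adjusted over the list alone, 2 cholesterol, 5 stress response and 2 glycolysis and hypoxia genes fell and 1 matrix gene rose. The 13 lists called became 8 without control replicate 3, which ended the calls of the neuronal, synapse, Notch, G1/S and matrix lists. DUSP5 lost its call without control replicate 3 or any 1 siRNA 2 library, NHLH2 without control replicate 3 (adjusted p = 0.0521) and ASNS without siRNA 2 replicate 1 (adjusted p = 0.0561). The neuronal call was also lost without control replicate 2, siRNA 1 replicates 1 or 2, or siRNA 2 replicates 1 or 3, and the synapse call without control replicate 2 or siRNA 2 replicates 1 or 2. The matrix call was also lost without control replicate 2 or siRNA 2 replicates 1 or 3, the Notch call without control replicate 1 or siRNA 2 replicate 2, and the G1/S call without siRNA 2 replicate 2. That of the ribosomal proteins was lost without control replicate 2 or siRNA 2 replicate 1. The highest adjusted p among these was 0.475, for the Notch list.

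In all, 104 genes passed the edgeR test with siRNA 2, 88 higher and 16 lower. The count was 32 without control replicate 3, 41 without siRNA 2 replicate 1 and 45 without siRNA 2 replicate 3. It was 235 with DESeq2, 237 without a filter on low counts and 20 with limma on log2(TPM + 1).

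Both siRNAs together changed 83 genes in the same direction, 72 higher and 11 lower. The 72 held 20 interferon response genes and 16 p53 targets. Among those that met the naming rule, ranked by the smaller of the 2 changes, OAS2, OAS1, MX1, OAS3, SAMD9, IFIT1 and EPSTI1 led, all induced by interferon, and IFIT3, IFIT2 and the viral RNA sensor gene IFIH1 were also among the first 12. PHLDA3, a p53 target that restrains AKT, rose by 1.45 with siRNA 1 and 1.40 with siRNA 2, and the cytokine gene LIF by 1.47 and 1.33. Beside GNL3, the genes lower with both that met the naming rule were F13A1, LRRC17, ALPK2, SEMA3C, GCNT4, DOCK9, CRISPLD1 (−0.60 and −0.57), ASNS (−0.54 and −0.68) and the translation inhibitor gene PDCD4 (−0.47 and −0.64). All 9 of these lost the siRNA 2 call without siRNA 2 replicate 1, 8 without control replicate 3 or siRNA 2 replicate 3, 7 without siRNA 2 replicate 2, 4 without control replicate 1 or siRNA 1 replicate 3, and 1 without control replicate 2 or siRNA 1 replicate 1. The siRNA 1 calls of F13A1, GCNT4 and PDCD4 were lost without control replicate 3 or siRNA 1 replicate 2, among other libraries. IFIH1 lost its siRNA 2 call without control replicates 2 or 3, siRNA 1 replicate 3, or siRNA 2 replicates 1 or 3.

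Of the 104 genes called with siRNA 2, 79.8% were also called in the same direction with siRNA 1. Independent lists of these sizes would share 3.32 genes higher with both and 0.48 lower with both. When all libraries, controls included, were simulated as unchanged from the control means, 0.1 genes were shared on average over 20 simulations, and 1 at most. The real control libraries were not used there and genes varied independently, so a chance deviation of many genes together could not appear. The 3 control libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls. The count of 83 was 30 without control replicate 3, 36 without siRNA 2 replicate 1, 41 without siRNA 2 replicate 3, 161 with DESeq2, 157 without a filter on low counts and 12 with limma on log2(TPM + 1).

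**Figure D3:**
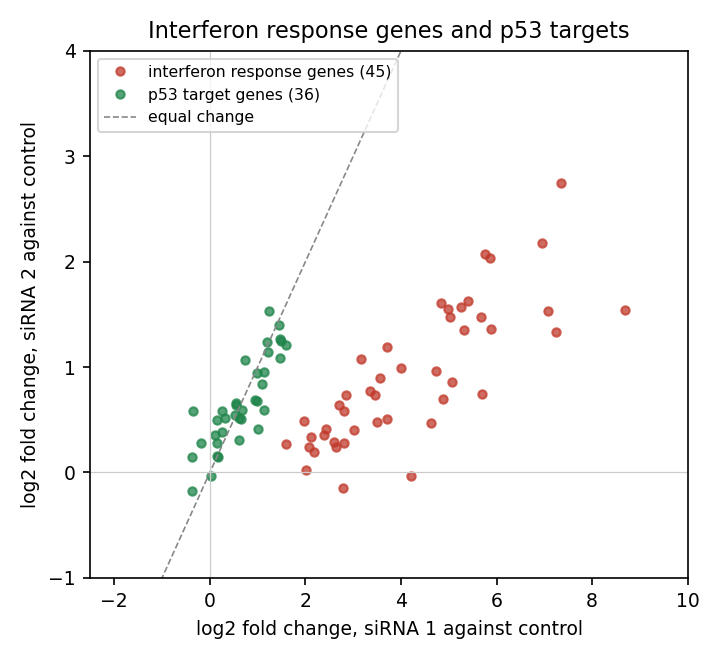
Log2 fold change against control with siRNA 1 (horizontal) and siRNA 2 (vertical) for 45 interferon response genes and 36 p53 target genes, with 1 point per gene; the 2 axes have different scales, IFNB1, with no control reads, is left out, and the dashed line marks equal change. Interferon response genes spread far to the right of that line, with medians of 3.85 and 0.76 over the whole list, while p53 targets lie near it, with medians of 0.64 and 0.59.

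Across the 20214 genes, the log2 fold changes of the siRNAs correlated with a Pearson r of 0.42 and a Spearman coefficient of 0.42; genes are not independent replicates, and r was 0.41 without the interferon response genes. Unchanged groups and controls, all simulated from the control means, gave an r of 0.50 and a covariance of 0.0849, beside an observed covariance of 0.138. The observed same-sign share was 66.1%, beside 66.6% in the simulations.

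Compared directly, the siRNAs differed most in the interferon response. All 46 measured genes of that list were higher with siRNA 1 than with siRNA 2, also when adjusted over the list alone, with a median difference of 3.11 (camera adjusted p = 1.52e-89; adjusted p = 0.00798 with an estimated correlation). RSAD2 was 7.15 higher on the log2 scale (SE 0.16, edgeR adjusted p = 1.77e-14), RTP4 7.11, the guanylate-binding gene GBP4 6.94, the inflammatory caspase gene CASP1 6.04 and OASL 5.90. Lower with siRNA 1 than with siRNA 2 were IL33 at −1.81, MMRN1 at −1.73, the protease inhibitor gene PI15 at −1.62, ANKRD1 at −1.28 and S100B at −1.20. The p53 list did not pass the test of the difference (median 0.02, camera adjusted p = 0.914), although its mean of −0.01 has the other sign. Within it TNFRSF10B and SESN2 were higher with siRNA 1, by 0.54 and 0.59, and the growth factor gene KITLG lower, at −0.95, with 2 higher and 2 lower when adjusted over the list alone. TNFRSF10B lost that call without siRNA 1 replicate 3 or siRNA 2 replicates 1 or 3, and SESN2 without control replicate 3, siRNA 1 replicates 2 or 3, or siRNA 2 replicates 1 or 3.

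Pluripotency markers were lower with siRNA 1 than with siRNA 2, with a median difference of −0.32, NODAL at −1.16 and LEFTY1, an inhibitor of NODAL signalling, at −1.15. Also called were DPPA2 at −0.70 and DNMT3B at −0.46, and 10 of 18 members when adjusted over the list alone (camera adjusted p = 2.06e-05; adjusted p = 0.111 with an estimated correlation). Glial markers had a median difference of −0.36, with 3 lower, among them S100B and the glutamate transporter gene SLC1A2 (−0.92), CNP higher (1.34), and 1 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.00927; adjusted p = 0.124 with an estimated correlation). In the G1/S list SLBP, PRIM1 and DSCC1 were lower, at −0.50, −0.46 and −0.53, and 4 members were when adjusted over the list alone (camera adjusted p = 0.00815; adjusted p = 0.468 with an estimated correlation). Stress response genes were higher by a median of 0.18, with TRIB3 at 1.08, ATF3 at 0.74, SESN2 at 0.59 and SHMT2 at 0.50, and 9 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0108; adjusted p = 0.468 with an estimated correlation). The glial call was lost without siRNA 1 replicate 1 (adjusted p = 0.0513) and the stress response call without siRNA 1 replicate 3 (adjusted p = 0.0528). Of the genes named here, DPPA2, DNMT3B, SLC1A2, SLBP, PRIM1, DSCC1, ATF3 and SHMT2 lost their calls in 3 to 7 of the 9 fits without 1 library, siRNA 1 replicate 2 and siRNA 2 replicate 3 among them each time.

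In all, 580 genes differed between the siRNAs by the edgeR test, 378 higher and 202 lower with siRNA 1. The count was 308 without siRNA 2 replicate 1, 304 without siRNA 2 replicate 3, 907 with DESeq2, 1042 without a filter on low counts and 201 with limma on log2(TPM + 1). The 5 lists called became 8 without siRNA 2 replicate 1.

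**Figure D4:**
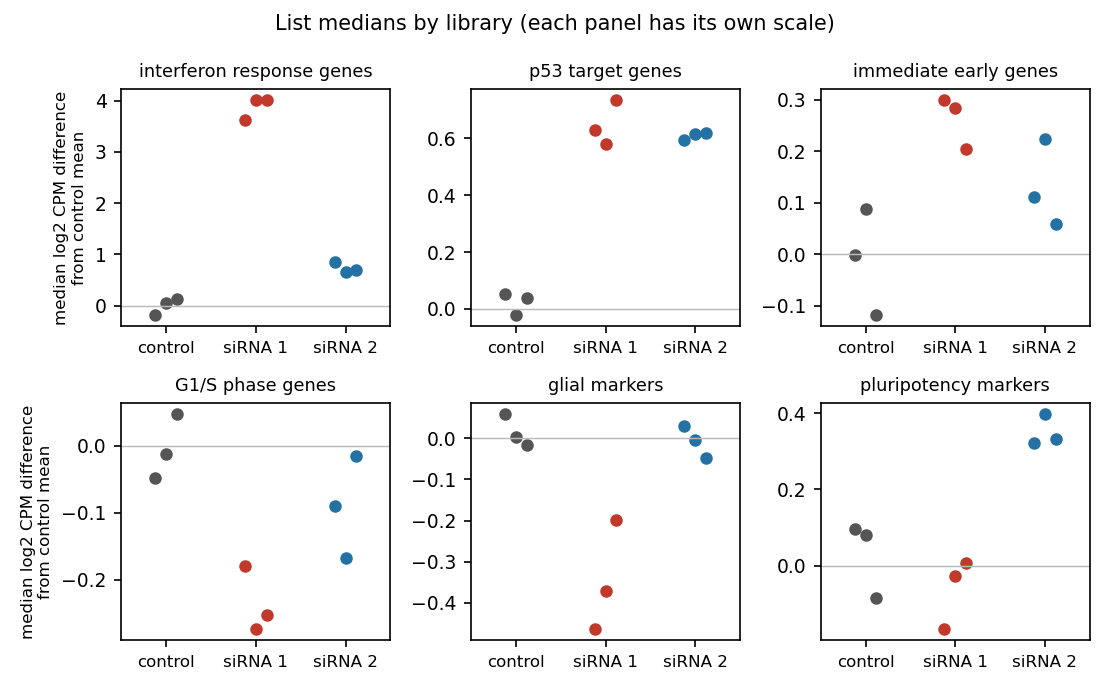
Median over each list's genes of the log2 CPM difference from the control mean, with 1 point per library and a separate scale in each panel. Interferon response genes and p53 targets lie above all controls in all 6 knockdown libraries, and pluripotency markers lie above the controls with siRNA 2 but not with siRNA 1.

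The 23 other lists did not pass the camera test with siRNA 1 (adjusted p from 0.103 to 0.961), and several held members that changed. Of 25 cholesterol synthesis genes, 5 fell, among them IDI1 by 0.71, HMGCS1 by 0.59, MSMO1 by 0.84 and SC5D by 0.89, and TM7SF2 rose by 0.75. Of 35 unfolded protein and integrated stress response genes, 6 rose, with SESN2 at 1.00 and TRIB3 at 0.92, and 5 fell, with the amino acid transporter gene SLC7A5 at −0.62 and ASNS at −0.54. The heat shock genes HSPE1, HSPH1 and HSPD1, chaperones, fell by 0.58, 0.60 and 0.40, of 20 measured. Of 44 extracellular matrix genes, 7 fell, among them TIMP3 by 0.64, TGFBI by 0.57 and LOX by 1.10. Of 28 neural progenitor markers, VIM, LIX1 and SLC1A3 fell, by 0.71, 0.98 and 0.50, and OTX2 rose by 0.40. Of 24 mesenchymal and neural crest markers, POSTN, PDGFRB and ACTA2 fell, by 0.76, 0.81 and 0.46. Of 18 pluripotency markers, DPPA2, L1TD1 and LEFTY1 fell, by 0.70, 0.55 and 0.69. Of 44 neuronal markers, NHLH2 rose by 1.54 and CALB2 and SCG3 fell by 1.03 and 0.46, and of 45 synapse genes the glutamate receptor gene GRIA1 rose by 1.03. Adjusted over the list alone, 1 cholesterol gene rose and 6 fell, 8 stress response genes rose and 7 fell, 6 heat shock and 9 matrix genes fell, and 2 mesenchymal genes rose and 4 fell; the other counts of this paragraph stayed as given. The calls of HMGCS1, TRIB3 and LOX were lost without control replicate 3 alone. Those of MSMO1, TM7SF2, HSPH1, HSPD1, SLC1A3, OTX2, ACTA2, L1TD1, LEFTY1, CALB2 and SCG3 were lost without control replicate 3, among other libraries, that of SC5D without siRNA 1 replicates 1 or 2 and that of DPPA2 without siRNA 1 replicate 2, with adjusted p of up to 0.219.

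Among signalling lists with siRNA 1, 3 of 25 Notch pathway genes rose, HES4 by 1.89, DTX4 by 0.49 and RFNG by 0.76, and 6 when adjusted over the list alone. Of 39 Wnt pathway genes RNF43, a ubiquitin ligase that removes Wnt receptors, rose by 1.09. Of 41 axon guidance genes, UNC5B, SEMA3A and EFNB2 rose, by 0.77, 0.56 and 0.47, and SEMA3C, SEMA3D and SEMA6D fell, by 0.73, 0.71 and 0.51, with 3 higher and 4 lower when adjusted over the list alone. Of 36 glycolysis and hypoxia genes, ADM, PFKL and ENO2 rose, by 0.81, 0.58 and 0.48, and the oxygen sensor gene EGLN3 fell by 0.71, with 3 higher and 4 lower when adjusted over the list alone. Of 40 DNA repair genes, RAD54B, the replication stress kinase gene ATR and RBBP8 fell, by 0.61, 0.46 and 0.48, and 5 when adjusted over the list alone. Of 15 shelterin and telomerase genes, TERF1 fell by 0.50 and TINF2 rose by 0.48. Of 69 ribosome biogenesis factors, GNL2 and NOP58 fell, by 0.43 and 0.44, and none passed when adjusted over the list alone. Of 9 endothelial and blood cell markers TEK fell by 0.35, and of 6 GNL3-related GTPases GNL2 did. Each of the calls of DTX4, RFNG, SEMA3A, EFNB2, SEMA3D, SEMA6D, PFKL, ENO2, RAD54B, ATR, RBBP8, TERF1, TINF2, NOP58 and TEK was lost without control replicate 3, among other libraries, with adjusted p of up to 0.251. The TEK call was lost in all 9 fits without 1 library, and that of ENO2 in 8.

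The cytosolic ribosomal proteins (77 measured), nuclear oxidative phosphorylation genes (43), mitochondrially encoded genes (15) and replication-dependent histone genes (22) had 0 members called with siRNA 1 by edgeR, 15 at an unadjusted p under 0.05 and 5 called by DESeq2. Their camera adjusted p were 0.130, 0.502, 0.226 and 0.832. With siRNA 2, 16 lists did not pass the camera test (adjusted p from 0.220 to 0.952), and of their members SEMA3C alone was called by edgeR. In the 21 lists with 0 members called with siRNA 2, 64 of 677 members were at an unadjusted p under 0.05 and DESeq2 called 7. Between the siRNAs, 24 lists did not pass (camera adjusted p from 0.0507 to 0.997), and several held members that differed. With siRNA 1, 4 extracellular matrix genes and 3 mesenchymal and neural crest markers were lower, and 2 glycolysis and hypoxia genes higher. Of 69 ribosome biogenesis factors, NOLC1 and DDX21 were lower with siRNA 1, at −0.58 and −0.45. DDX21 lost that call without control replicate 3, any 1 siRNA 1 library, or siRNA 2 replicates 1 or 3, with adjusted p of up to 0.294. In the 11 lists with 0 members called between the siRNAs, 36 of 303 members were at an unadjusted p under 0.05 and DESeq2 called 4. Among the lists not called, median and test had different signs for the glial markers, the neighbours of GNL3 and the GNL3-related GTPases with siRNA 2, for the neighbours with siRNA 1, and for the synapse genes and p53 targets between the siRNAs.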

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

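The tests of the GNL3 difference, of scaling and of interferon transcripts were chosen only after the result was seen. Between the siRNAs, 580 genes differed by the direct edgeR test, which means that the effects of the siRNAs relative to the same controls differ. The lists that differed in the direct camera test were the interferon response genes (adjusted p = 1.52e-89), pluripotency markers (adjusted p = 2.06e-05), G1/S phase genes (adjusted p = 0.00815), glial markers (adjusted p = 0.00927) and the unfolded protein and integrated stress response genes (adjusted p = 0.0108). With an estimated correlation, of these 5 only the interferon response genes passed (adjusted p = 0.00798); the others had adjusted p = 0.111, 0.468, 0.124 and 0.468. The glial call was also lost without siRNA 1 replicate 1 (adjusted p = 0.0513), and the stress response call without siRNA 1 replicate 3 (adjusted p = 0.0528). The count of 580 was 308 without siRNA 2 replicate 1 and 304 without siRNA 2 replicate 3. Among named genes, RSAD2, RTP4, GBP4, CASP1 and OASL were higher with siRNA 1, by 7.15, 7.11, 6.94, 6.04 and 5.90 on the log2 scale. The differences of IL33, MMRN1, PI15, ANKRD1 and S100B were −1.81, −1.73, −1.62, −1.28 and −1.20, and none of these 10 calls was lost without any 1 library.

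The pattern weighed here is the rise of interferon response genes, with medians of 3.85 with siRNA 1 and 0.76 with siRNA 2. Deeper loss of GNL3 as the cause is argued against by a GNL3 difference of −0.11 (SE 0.11) between the siRNAs, and scaling between libraries by a largest difference of 0.0545 in any gene's log2 fold change between scaling methods. Of 7 leukocyte genes, 0 were called higher with siRNA 1 by edgeR, but only 3 had enough reads to be tested. Of these 3, 0 were at an unadjusted p under 0.05 or called by DESeq2. PTPRC averaged 0.0977 CPM against 0.133 in controls, and AIF1, the most abundant, 1.88 against 2.70. CD68, not tested, went the other way, at 0.269 against 0.0190, and so did ITGAM, at 1.21 against 0.884. These levels are low and go both ways, so they cannot decide whether immune cells were a source. IFNB1 had 167 reads in the siRNA 1 libraries and IFNL1 71, with 1 read of the pair in the other 6 libraries, beside 79, 56 and 45 reads of the constitutive IFNK with siRNA 1, siRNA 2 and control, so the siRNA 1 cells may have made interferon themselves. That is a hypothesis, and what set it off stays open: the siRNA sequences are not given in the sources used here, and the controls, described as siRNA samples too, had 0 reads of IFNB1.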

How the results depend on the processing

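The fits on protein-coding genes only and with the GC and length trend removed were chosen after seeing the data. Over counts of genes, GNL3 and the correlation, 157 of 195 alternative values stayed on the same side or within 1.5 times, 37 moved, 1 was weaker and 0 reversed; for the genes and lists called, 3083 of 3569 and 255 of 312 kept direction and call, and the rest lost the call. Genes called with siRNA 1, siRNA 2, between the siRNAs and with both were 2065, 235, 907 and 161 with DESeq2 and 196, 20, 201 and 12 with limma-trend on log2(TPM + 1). At an absolute log2 fold change of at least 1 they were 398, 47, 306 and 35, fewer by construction. Without a filter on low counts, siRNA 2, the direct comparison and both gave 237, 1042 and 157. With the GC and length trend removed, siRNA 2 gave 220 and both 158. The GNL3 fold change with siRNA 2 on log2(TPM + 1) was −0.83, no longer past the threshold. The cause was not tested for these, except where the construction shows it. Leaving out 1 library gave 590 to 1747, 32 to 112, 304 to 727 and 30 to 86 genes, GNL3 fold changes of −1.42 to −1.30 and −1.32 to −1.17, and a correlation of 0.32 to 0.54. Lists called numbered 2, 2 and 1 of 6, 13 and 5 with an estimated correlation, which gave the highest adjusted p of the 13 alternatives for all 24 calls, 4 with fry for siRNA 2, and 5 to 13, 8 to 16 and 5 to 8 without 1 library. With the replicate number as a block the counts were 2168, 106, 933 and 86. Same-numbered siRNA 2 and control libraries correlated in their deviations at 0.17, 0.21 and 0.10, each best with its own number, but siRNA 1 and control at −0.12, −0.01 and 0.00, so the numbers were not taken to pair samples. Depth and 3 libraries per group limit calls of small changes. In simulation 43.3% of genes changed 1.5-fold were called with siRNA 1 and 48.5% with siRNA 2. Only genes with a mean of at least 5 CPM were changed there, so these shares do not cover less abundant genes.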

Other observations

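The tests of the pluripotency pattern and the genes of this paragraph were chosen only after the result was seen. Of the 72 genes higher with both siRNAs by the edgeR test, 34 were in no fixed list, and 4 of these are given here as single genes. TNFRSF10A and TNFRSF10C, which code for receptors of the death ligand TRAIL, rose by 1.43 and 1.97 with siRNA 1 (adjusted p = 1.59e-05 and 6.27e-06) and by 1.03 and 1.24 with siRNA 2 (adjusted p = 0.00514 and 0.00845). DRAM1, a lysosomal gene of autophagy, rose by 1.24 and 1.05 (adjusted p = 9.82e-05 and 0.00493), and GLS2, a mitochondrial glutaminase gene, by 0.85 and 0.83 (adjusted p = 7.09e-04 and 0.00633). The siRNA 2 calls were lost for TNFRSF10A without siRNA 2 replicate 1, for TNFRSF10C without control replicate 3 or siRNA 2 replicate 2, for DRAM1 without control replicate 3, and for GLS2 without control replicate 3 or siRNA 2 replicate 3. MIR205HG rose more with siRNA 2 than with siRNA 1, with a difference of −1.09 (adjusted p = 2.79e-05). AC117498.1, named as a clone and so outside the naming rule, was the 1 gene called in opposite directions. It stood at 2.18 with siRNA 1 and −4.15 with siRNA 2, both near the threshold (edgeR adjusted p = 0.0284 and 0.0413).

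Pluripotency genes were abundant in every library and PAX6, SOX1 and HES5 scarce, while OTX2 and SOX11, also on the list of neural progenitor markers, averaged 104 and 184 CPM. Reads of POU5F1 copies as the whole cause are argued against by 12 of 18 pluripotency genes above 10 CPM in all 9 libraries. Carry-over in some libraries only is argued against by a largest ratio of 1.59 between the highest and lowest library for POU5F1, LIN28A and DPPA4, although L1TD1 and NANOG varied more, at 1.98 and 2.38. The lowest ratio of POU5F1 to PAX6 was 334 and the highest 893, which restates the pattern and is no separate test of it. The cells may have been in a state closer to pluripotency than the label neural progenitor says. A culture of mixed states in the same proportions in every library stays open.

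siRNA 1 changed more genes than siRNA 2, 1373 against 104 or 13.2 times as many; the counts were 1747 against 71 without control replicate 2, 1033 against 41 without siRNA 2 replicate 1, 1071 against 45 without siRNA 2 replicate 3 and 709 against 112 without siRNA 1 replicate 2. Off-target binding through the siRNA 1 seed was searched for in words of 7 bases of 3′ untranslated regions. The lowest score was −3.99, beside −4.92 in the permutations. That argues against a seed effect beyond the permutations, as far as words in annotated regions can show, and a weaker one stays open. The lowest word, AGCAGCA, is found in a GNL3 transcript. Between the siRNAs, the overlapping words TAGCAGC, CTAGCAG and AGCAGCA ranked 3 to 5 from the lowest, and of these only AGCAGCA is in a GNL3 transcript. Their scores were −3.74, −3.67 and −3.58, beside −5.13 in the permutations. GC content and transcript length as the whole cause are argued against by a ratio of 6.93 after their trend was removed. A single aberrant siRNA 1 library is argued against by a lowest ratio of 6.33 without each siRNA 1 library in turn. Other differences between the siRNAs stay open and could include the interferon response, whose effect on other genes was not tested.

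The 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 1373 genes with siRNA 1 and 20 at most in the others, 104 with siRNA 2 and 2 at most, and 580 between the siRNAs and 2 at most; in each, 1 of the 10 splits gave as many, the real one. Of 100 drawn splits of the 9 libraries, of 840 possible, 2 gave at least 83 genes called with both, a share under 0.05. That argues against groups that do not differ at all. Such splits cannot tell whether the siRNAs agree beyond their shared controls, because a change with siRNA 1 alone already makes the groups differ. The highest other split gave 473 genes. It kept the siRNA 1 libraries together as the common reference, so its count holds the difference between siRNA 1 and the other libraries.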
